A study of Mus musculus with 2 samples.

How the data were processed

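Whole intestine from mouse embryos was profiled by total RNA sequencing in 2 libraries. Per the labels, RNA was extracted with the mirVana method, the size range was over 200 nt, ERCC spike-ins were added and 10 ng went into each library. The labels also cite the manual of a SMARTer kit for low RNA input, but how it was applied, and whether libraries kept strand, is not given in the sources used here. Reads from a gene and an overlapping antisense gene may therefore not be separable.

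Each library came with a gene table and a transcript table. Per the file headers and the text deposited beside them, reads were assigned to transcripts of GENCODE M4 on genome mm10, and the aligner, the quantifier and their versions are not given in the sources used here. The deposited expected counts are estimated reads per feature, not normalised, in which reads shared between features are divided, so they need not be whole. The deposited TPM values divide these counts by effective length and scale all features, spike-ins included, to the same total in each library, and the deposited FPKM values scale by length and assigned reads. Effective length was the length minus 99 in the tables. Short features of effective length 1 to 99 held 0.0225% and 0.0218% of counts but 1.00% and 1.06% of TPM. The deposited percent values give each transcript's share of its gene. The deposited intervals of TPM come with posterior means, and their level is not stated in the files.

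Of 43346 gene identifiers, 42462 (98.0%) matched GENCODE M21, from which symbols, gene types and mm10 coordinates were taken. The 884 others held 0.157% and 0.152% of counts. A further 26248 features with numeric identifiers name no gene and held 0.000147% and 0.000157% of counts, and they stayed out of the tests. Expected counts over genes were 41279206 and 40758084, and the spike-ins with at least 3 counts numbered 76 and 75 of 96. Counting floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

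Levels were summarised as mean and SD over the 2 libraries. Replicate agreement used log2(TPM + 1). Replicate spread used edgeR 4.0.16 in R 4.3.3 on expected counts rounded to whole numbers, with TMM normalisation and a minimum of 10 counts in both libraries. The list difference used log2 ratios of TPM with a pseudocount of 0.1, relative to the median of expressed protein-coding genes (0.01 removed). It covered lists with at least 5 protein-coding members at a mean TPM of at least 1, and only those members. Each list median was ranked among 10000 random lists matched in 20 expression bins. Gene differences required a mean count of at least 100, a 2-fold ratio and intervals apart. Other computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. No paired analysis was possible because there is 1 group.

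The 43 gene lists, the 22 pairs, the comparisons of the Results and the alternatives were fixed before the data were examined, whereas the tests of explanations in the closing section were written later, 3 of them after their results were seen. The genes named were the 20 most abundant protein-coding genes not encoded by mitochondria, the 3 highest members and the lowest of each list with all members of lists of 6 or fewer, the 10 genes farthest apart in each direction between libraries, the pair genes, the Hox genes and the fixed isoform genes. A few genes and pairs that this rule takes in are not reported here. Genes of 5 further lists, which test explanations in the closing section, were written down after the first results and before their own values were seen.

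The procedures were tested on simulated data for 13502 genes. For the gene difference, 98.0% of 100 genes changed by log2 1.5 and 100% of 100 changed by log2 3 were recovered, and 0% of 12526 unchanged genes were called. Every simulated gene had a coefficient of variation of 0.1 and intervals of counting error only, which left unchanged genes little room to reach 2-fold. In the libraries the coefficient rose to 0.167 for the least expressed genes, so 0% is not the rate of false calls in the data. For the list difference, a list shifted by 0.5 gave a median of 0.49, and 2 of 100 unshifted lists lay outside the central 95%. A true coefficient of variation of 0.1 was recovered as 0.099 with no gene changed and as 0.167 with 200 genes changed. Alternatives were other pseudocounts, filters, fold minimums, normalisations (TMM, DESeq2 1.42.0 size factors), posterior means, counts without length, and each library left out.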

Results

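Total RNA longer than 200 nt was sequenced from the intestine of B6NCrl mouse embryos at embryonic day 16.5, when the gut tube already carries villi. The series holds 2 libraries of 1 group, named replicate 1 and replicate 2, each made from 10 ng of RNA. Each library came from its own pool of male and female embryos, and the labels list the pools as separate biosamples under the same donor identifier. Replicate 2 was pooled from 41 embryos, and the number for replicate 1 is not given in the sources used here. The libraries held 42040766 and 41480301 expected counts, of which 94.3% and 94.5% fell on protein-coding genes. Artificial ERCC spike-in transcripts took 1.81% and 1.74% of the counts, and mitochondrial genes took 1.85% and 1.81%. With a single group, the comparisons were between genes and gene lists within the tissue and between the 2 pools. Levels are in TPM, a measure of abundance corrected for transcript length, and are given as mean ± SD of the 2 libraries (n = 2) unless both values are shown, and a gene was called detected at a TPM of at least 1 in both.

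Apart from genes encoded by mitochondria, which were left out of this ranking and took 3.40% and 3.36% of TPM, the most abundant protein-coding transcripts came from red blood cells, the cytoskeleton and absorptive cells. Adult alpha-globin Hba-a2 (ENSMUSG00000069917.7; mm10 chromosome 11, 32296489 to 32297298) led at 8633 ± 1252 TPM, with Hba-a1 at 3440 ± 479 and the adult beta-globins Hbb-bs at 4593 ± 532 and Hbb-bt at 2948 ± 509. The adult globins together took 1.96% ± 0.277 of all TPM. Ferritin light chain Ftl1 stood at 6275 ± 259 and beta-actin Actb at 6099.8 ± 406. Fabp1 (ENSMUSG00000054422.7; chromosome 6, 71199827 to 71205023), which carries fatty acids inside enterocytes, reached 4527 ± 991, and the lipoprotein component Apoa1 reached 3197 ± 637. The metal-binding Mt1 stood at 3163 ± 35.6, the glycolytic enzyme Ldha at 2656 ± 76.5 and the histone gene Hist1h2ap at 2252 ± 252. Pnliprp1 (ENSMUSG00000042179.5; chromosome 19, 58728887 to 58744169), a lipase-related protein of the pancreas, was the 20th gene of this ranking at 2152 ± 251. Its top 20 genes summed to 7.34% ± 0.122 of TPM and the top 100 to 18.4% ± 0.0117. Of 21474 protein-coding genes, 13311 (62.0%) were detected, 8251 reached a TPM of 10, 1604 reached 100 and 102 reached 1000. Among 2777 lincRNA genes, 189 were detected. The alpha-globins, the beta-globins and Hist1h2ap have near-identical copies, so the split of reads within each family is uncertain.

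Epithelial identity genes were all detected, 16 of 16, with a median of 257 ± 15.2 TPM. Lgals4, a lectin of the intestinal epithelium, stood at 2141 ± 106, the tight junction gene Cldn7 at 1199 ± 19.8 and keratin Krt8 at 968 ± 33.2, and the lowest member, Tjp3, at 36.3 ± 1.27. Absorptive function was uneven. Of 19 enterocyte genes, 16 were detected, led by Fabp1, Fabp2 at 1492 ± 497 and the brush-border phosphatase Alpi at 257 ± 53.3. Lct, the lactase of suckling animals, was at 53.6 ± 21.04, whereas Sis, the sucrase-isomaltase of the weaned gut, was at 0.765 ± 0.233, a log2 ratio of 6.11 ± 1.03, with 5.38 in replicate 1 and 6.83 in replicate 2, and 7.29 in counts without length. Tmprss15, which encodes enteropeptidase, had 0 and 2 counts. All 14 lipid absorption genes were detected, from Apoa1, Apoa4 at 2047 ± 807 and Apoc3 at 619 ± 197 down to the sterol transporter Abcg8 at 1.42 ± 0.530. Protein uptake genes were present in all 6 cases: the IgG receptor Fcgrt at 325 ± 69.5, Amn at 219 ± 43.3, Dab2 at 55.0 ± 10.9, Pllp at 36.9 ± 2.93, Cubn at 9.49 ± 3.11 and Lrp2 at 1.79 ± 0.078. All 19 intestinal transcription factors were detected, with Creb3l3 at 129.9 ± 34.3, Isx at 89.7 ± 4.48 and Hnf4g at 86.6 ± 10.7 highest and Foxa1 lowest at 2.65 ± 0.233.

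Secretory cell genes differed by lineage. Goblet genes were detected in 8 of 9 cases, with trefoil factor Tff3 at 1142 ± 39.3, Spink4 at 469 ± 12.9 and Agr2 at 358 ± 13.8, while Retnlb had no count in either library, where a count of 0 allows up to 3. Enteroendocrine genes were detected in 17 of 20 cases, led by the hormones secretin (Sct, 266 ± 18.02), ghrelin (Ghrl, 124 ± 4.12) and proglucagon (Gcg, 65.0 ± 11.2). Paneth cell genes were detected in 5 of 9 cases. The defensins Defa24 and Defa17 stood at 197 ± 19.4 and 151 ± 24.7, with Lyz1 at 14.9 ± 0.233, and Pla2g2a, Defa21 and Defa22 had no count. Defensin genes have near-identical copies, so these values name a family better than a gene. Of 7 tuft cell genes, 2 were detected, Trpm5 at 6.83 ± 0.092 and Dclk1 at 3.99 ± 0.198. Il25, the lowest, stood at 0 and 0.11 TPM. Stem and progenitor genes were all detected, 17 of 17, at a median of 7.37 ± 0.523, with Smoc2 at 99.3 ± 2.41, Prom1 at 24.0 ± 0.757, Bmi1 at 10.5 ± 0.389 and Axin2, the lowest, at 2.57 ± 0.226. Lgr5 stood at 3.91 ± 0.587 and Olfm4 at 9.87 ± 0.601. The 5 fetal epithelium genes were all detected, among them Clu at 64.8 ± 0.049, Anxa1 at 47.4 ± 4.62, Gja1 at 27.3 ± 0.177 and Ly6a at 12.7 ± 1.10.

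Genes of the muscle, connective tissue, nerves and vessels of the gut wall were also present. All 15 smooth muscle genes were detected, led by the actins Actg2 (1484 ± 13.7) and Acta2 (1417 ± 74.3) and by Myl9 (1063 ± 17.6), with Synm lowest at 3.33 ± 0.594. All 14 mesenchyme and matrix genes were detected at a median of 259 ± 2.45, with Sparc at 1457 ± 28.9, collagens Col3a1 at 1247 ± 59.9 and Col1a1 at 813 ± 73.0, and Dpt lowest at 14.1 ± 0.608. The pacemaker cells of the gut, the interstitial cells of Cajal, were represented by Etv1 at 24.1 ± 0.643, Ano1 at 17.0 ± 0.304, Kit at 12.9 ± 0.318 and Prkcq at 1.21 ± 0.12. Enteric progenitor and glial genes were detected in 10 of 12 cases, with Ednrb at 97.0 ± 3.64, Fabp7 at 29.6 ± 2.26 and Erbb3 at 27.6 ± 3.15, and with the mature glial gene Gfap lowest at 0.195 ± 0.177. Enteric neuron genes were detected in 12 of 16 cases, with Uchl1 at 62.8 ± 3.79, Stmn2 at 43.3 ± 4.23, Tubb3 at 41.9 ± 4.26 and Nos1 lowest at 0.770 ± 0.014. All 13 endothelial genes were detected, from Egfl7 (97.3 ± 5.50), Plvap (64.0 ± 5.84) and Pecam1 (41.3 ± 0.212) to the lymphatic factor Prox1 (1.53 ± 0.042). The 5 mesothelial genes were detected as well: Upk3b at 59.3 ± 3.07, Msln at 20.3 ± 1.76, Upk1b at 11.4 ± 0.863, Wt1 at 7.73 ± 1.12 and Lrrn4 at 7.63 ± 1.27.

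Blood and proliferation genes formed a further layer. Of 12 erythroid genes, 10 were detected, with embryonic Hbb-bh1 lowest at 0.80 ± 0.368. All 12 macrophage and myeloid genes were detected, with Lyz2 at 77.1 ± 8.21 and the complement genes C1qb at 65.7 ± 0.721 and C1qa at 51.7 ± 0.177 highest, and Mrc1 lowest at 4.14 ± 0.269. Of 9 lymphoid genes, 2 were detected, among them Ltb at 3.89 ± 0.141. Cd3g stood at 1.18 ± 0.318, and the B-cell gene Ms4a1 was lowest at 0.040 ± 0.028. All 17 cell cycle genes were detected at a median of 118 ± 11.6, with Cdk1 at 304 ± 23.3, Birc5 at 241 ± 28.8, Cdc20 at 184 ± 14.5 and Mki67 lowest at 17.98 ± 1.252.

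Signalling lists were fully detected apart from Wnt. The 14 hedgehog genes had a median of 8.94 ± 0.417, with the target Foxf1 at 74.8 ± 0.721, the ligand Ihh at 22.7 ± 1.58, Hhip at 18.5 ± 0.70 and Shh lowest at 2.43 ± 0.028. The 14 BMP genes were led by the targets Id2 at 281 ± 11.5, Id3 at 204 ± 8.06 and Id1 at 86.7 ± 6.72, and the antagonist Nog was lowest at 1.16 ± 0.007. Of 21 Wnt genes, 16 were detected, with beta-catenin Ctnnb1 at 315 ± 3.95 and the secreted inhibitors Sfrp2 at 49.1 ± 1.69 and Sfrp1 at 43.6 ± 2.70 highest, and Rspo4 lowest at 0.030 ± 0.014. The 13 Notch genes had a median of 7.40 ± 0.318, with Hes1 at 26.5 ± 6.08, Dll1 at 21.1 ± 0.735, Rbpj at 16.8 ± 0.240 and Hes5 lowest at 1.17 ± 0.085.

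Genes of neighbouring organs were read beside these lists. Pancreatic genes were abundant in both libraries: 11 of 12 were detected, and the median of all 12 was 299.8 ± 64.7 TPM, above the epithelial median of 257 ± 15.2 by less than the SD of the 2 libraries. Besides Pnliprp1, the digestive enzymes Ctrb1 and Cela2a stood at 1860.5 ± 354 and 574 ± 261, whereas the lipase Pnlip was at 0.310 ± 0.014. All 12 liver genes were detected at a median of 20.0 ± 6.47, with Cps1, which the intestine also expresses, at 354 ± 57.3, the fetal protein Afp at 230.2 ± 64.5, Ttr at 88.7 ± 0.983 and Itih2 lowest at 4.32 ± 3.13. Of 13 stomach genes, 3 were detected, Tff2 at 5.28 ± 1.21, Tff1 at 2.86 ± 1.17 and Atp4a at 1.58 ± 0.445, and Muc5ac and Gif had no count. Of 9 urogenital and adrenal genes, 1 was detected, the steroid enzyme gene Cyp11a1, at 19.2 TPM in replicate 1 and 5.51 in replicate 2. Star stood at 6.26 and 0.570, Pax8 at 0.810 ± 0.042, and Umod had no count. Without replicate 2, 3 members of that list reached a TPM of 1. Of 8 skeletal muscle genes, 4 were detected, with Mylpf at 14.3 ± 1.71, Ckm at 10.8 ± 1.16 and Acta1 at 10.8 ± 1.99 highest and Myod1 lowest at 0.070 ± 0.042.

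**Figure D1:**
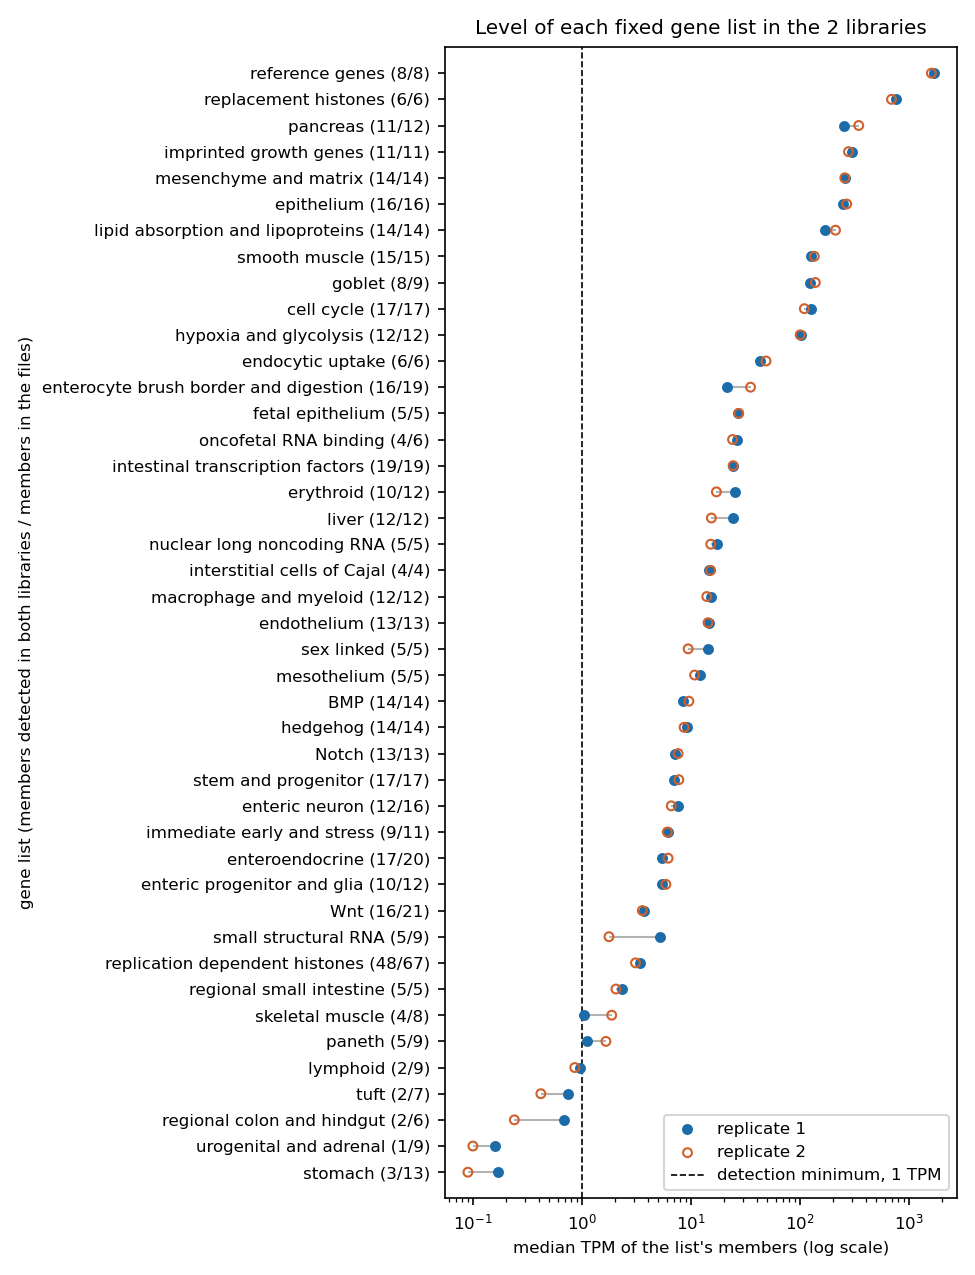
Median TPM of the members of each fixed gene list on a log axis, with a filled point for replicate 1 and an open point for replicate 2, and the detected and listed members in brackets. Averaged over the libraries, the pancreas list has a median of 299.8 TPM and epithelium 257.

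The whole-gut sample carried both small intestinal and hindgut positional genes. Small intestinal Gata4 stood at 26.1 ± 2.98, Fabp6 at 3.24 ± 1.67, Onecut2 at 2.34 ± 0.403, Pdx1 at 2.08 ± 0.389 and Slc10a2 at 1.22 ± 0.198, all 5 detected. Of the 6 colon and hindgut genes, 2 were detected, among them Hoxb13 at 4.39 and 1.64 TPM. Car1 was at 0.515 ± 0.460, Hoxd12 at 0.395 ± 0.177, Hoxa13 at 0.295 ± 0.12 and Hoxd13 at 0.215 ± 0.078. Of 39 Hox genes, the factors that set position along the body axis, 24 were detected. Hoxb5 (chromosome 11, 96303336 to 96306121) was highest at 23.5 ± 1.44, then Hoxa5 at 13.1 ± 0.12 and Hoxd3 at 12.2 ± 1.06. Paralogs 1 to 6 held 67.6% ± 2.06 of Hox TPM, and paralog 5 alone held 28.5%. By cluster, Hoxb held 39.4%, Hoxa 30.6%, Hoxc 15.1% and Hoxd 14.9%. Hoxc12 and Hoxc13 had no count in either library.

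**Figure D2:**
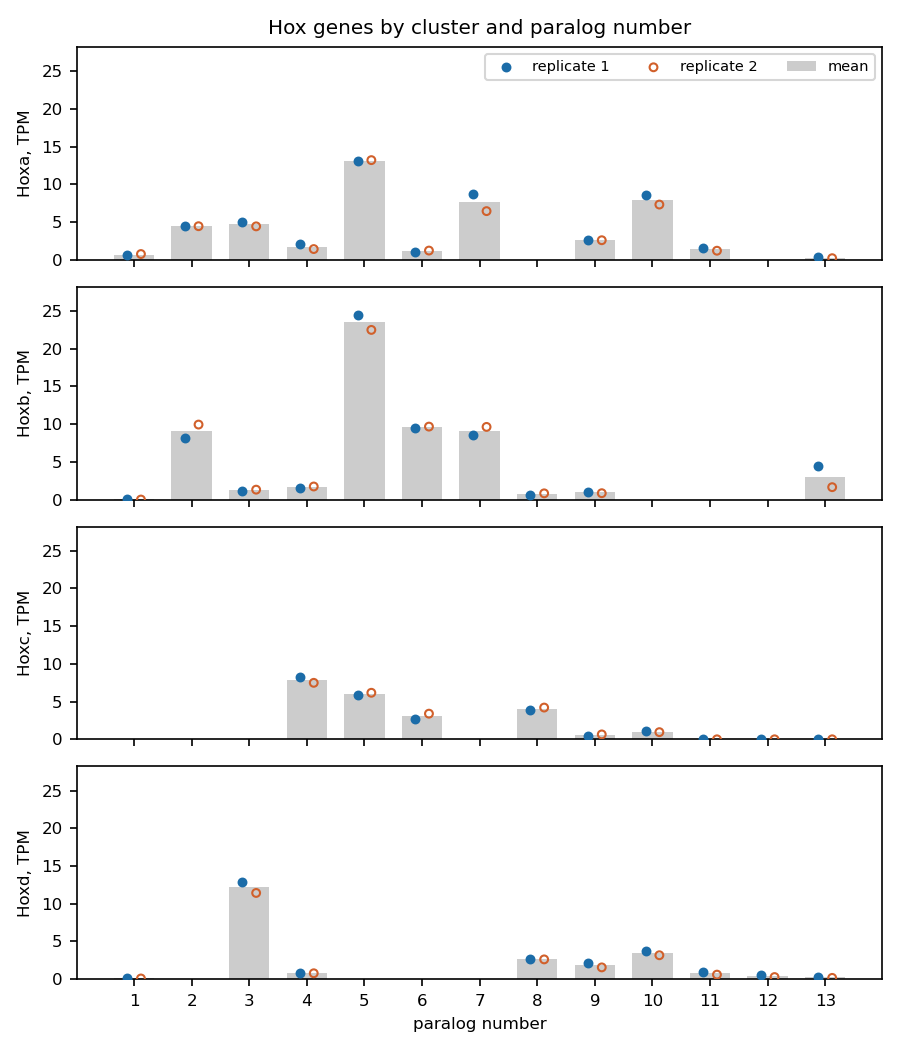
TPM of each Hox gene by paralog number in 4 panels, 1 per cluster, with bars for the mean and points for the 2 libraries. Hoxb5 is the tallest bar at 23.5 TPM, and Hoxb13 differs between the libraries, at 4.39 and 1.64.

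Ratios within fixed gene pairs asked which partner dominated. A pair was called apart when both libraries had the same sign and the mean log2 ratio exceeded 3 SD, and 17 of 22 pairs were. Of the hedgehog ligands, Ihh stood 9.33-fold above Shh (log2 3.22 ± 0.0840). Bmp4 stood 4.81-fold above Bmp2 and Hes1, a Notch target, 2.98-fold above Atoh1, the secretory fate factor. Fabp1 stood 3.08-fold above Fabp2. Cdx1 exceeded Cdx2 by 1.96-fold, Gata4 exceeded Gata6 by 1.31-fold and H19 exceeded Igf2 by 1.74-fold. Adult beta-globins exceeded the embryonic ones by 253-fold, and adult alpha-globins exceeded Hba-x by 1019-fold. Not apart were Hnf4a and Hnf4g, Apoa1 and Apoa4 (log2 0.69 ± 0.29, and -0.20 in counts without length), Pdgfra and Pdgfrb, Actg2 and Acta2, and Chga and Muc2. In counts without length, Hnf4a over Hnf4g (log2 0.44), Pdgfra over Pdgfrb (0.22) and Acta2 over Actg2 were called apart, each against its direction in TPM, and the ratio of Bmp4 to Bmp2 fell from log2 2.27 to 1.28 and that of Fabp1 to Fabp2 from 1.62 to 0.69. The remaining calls were low or changed with the unit. Olfm4 was 2.54-fold above Lgr5, Gli1 1.37-fold above Gli2, Notch2 1.24-fold above Notch1 and Lin28b 3.80-fold above Lin28a. The Lgr5 and Gli directions turned when counts were used without length, and the Notch and Lin28 directions turned with posterior mean TPM. Without length, Gata6 over Gata4 and Hes1 over Atoh1 kept their sign but were no longer apart. With 2 libraries, the smallest exact 2-sided sign-flip p is 0.5, so no p-value is given.

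Of 22 fixed genes, 19 had at least 2 annotated transcripts, and in 16 of these the same transcript was the major one in both libraries. Hnf4a-202 took 79.3% ± 1.65 of Hnf4a, Esrp1-204 took 61.8% ± 0.594 of the epithelial splicing factor Esrp1, Tcf7l2-209 took 36.9% ± 2.88 of Tcf7l2, Tpm2-203 took 97.8% ± 0.0283 of Tpm2 and Actn1-201 took 59.99% ± 1.39 of Actn1. The exceptions were Fn1, Kit and Vegfa. Kit-201 held 62.7% of Kit in replicate 1 and 40.0% in replicate 2. With posterior means the share of Hnf4a-202 was 54.97%. Across 7785 genes with at least 2 transcripts and a mean TPM of at least 5, the major transcript was the same in 7301 (93.8%, 95% Wilson interval 93.2 to 94.3). The interval treats genes as independent trials and does not measure the spread between libraries or animals.

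The RNA classes were compared through their list medians. The 6 replacement histone genes, whose mRNAs carry poly(A) tails, had a median of 728 ± 53.8 TPM, with H3f3a at 1470.4 ± 89.4, H2afz at 1126 ± 115, H3f3b at 1116 ± 88.4, H2afv at 344 ± 13.3, H1f0 at 342 ± 10.3 and H2afy at 204 ± 6.99. The 67 replication-dependent histone genes, whose mRNAs lack tails, had a median of 3.27 ± 0.233 (a log2 distance of 7.80 ± 0.00360), with 48 detected. This distance is between medians of lists of unequal size. Hist1h2ap, Hist1h4d (203 ± 25.8) and Hist1h2bc (159.9 ± 9.98) were exceptions near the top. Of 9 small structural RNAs, 5 were detected, and the median of all 9 was 3.50 ± 2.45, a log2 distance of 7.90 ± 1.00 below the replacement histones. Only RNA above a minimum size was sequenced, so members shorter than it would read low whatever their class. The lengths of the 9 were not compared with that minimum, so the distance to them does not separate class from size selection. The sums lay closer or the other way, at 3141 ± 327 TPM for replication-dependent histones, 16614 ± 3561 for small structural RNA and 4603 ± 323 for replacement histones, and in CPM at 932 ± 98.2, 2318 ± 472 and 3844 ± 320. The signal recognition particle copies Rn7s1 and Rn7s2 read 6967 TPM each in replicate 1, an equal split of shared reads, and 9472 and 9473 in replicate 2. Rn7sk stood at 114 ± 17.9, and Rny3 had no count. Both distances between medians exceeded the SD of the 2 libraries. Without division by length, in CPM, they were wider, at log2 9.22 and 11.48.

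The libraries ranked genes alike. Over 21474 protein-coding genes, log2(TPM + 1) gave a Pearson r of 0.997 and a Spearman rho of 0.993 across genes, which are not independent replicates, and the 96 spike-ins gave an r of 0.999. Among 13509 genes with a mean TPM of at least 1, 98.8% lay within 2-fold and 167 beyond. Reference genes showed the same: Actb, Ppia at 4555 ± 144 and Eef1a1 at 3589 ± 138 were highest of 8, Tbp was lowest at 28.2 ± 0.255, and the list median differed by 1.02-fold. The common biological coefficient of variation, estimated by edgeR from 17638 genes, was 0.105. Counts differed by more than counting noise, with a chi-square of 20.9 per degree of freedom in the mean and a median of 2.48 against 0.455 expected, so they are not 1 set of reads split in 2. They were kept as 2 replicates because the labels list separate samples, and the chi-square does not separate pools from preparations.

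Absorptive and pancreatic genes were higher in replicate 2, and liver, red-cell and proliferation genes were higher in replicate 1. Enterocyte genes were 1.42-fold higher in replicate 2 in the median, in 16 of 16 members, and lipid absorption genes 1.53-fold in 13 of 14. Fabp2 read 1141 and 1844 TPM in replicates 1 and 2, Apoa4 1477 and 2618, and Alpi 219 and 294. Pancreatic genes were also higher there, 1.32-fold in 11 of 11, with Cela2a at 389 and 759. Endocytic uptake genes were 1.34-fold higher in 5 of 6, transcription factors 1.11-fold in 16 of 19, goblet genes 1.10-fold in 5 of 8, epithelium 1.06-fold in 12 of 16 and mesenchyme 1.06-fold in 10 of 14. In the other direction, liver genes were 1.88-fold higher in replicate 1 in 11 of 12, Cps1 being the exception, with Afp at 276 and 185 TPM. Beside them, erythroid genes were 1.39-fold higher in 11 of 11, cell cycle genes 1.14-fold in 17 of 17, replication-dependent histones 1.16-fold in 31 of 50 and enteric neuron genes 1.14-fold in 12 of 14. The small intestinal list was 1.22-fold higher in 3 of 5 by its median, but its mean went the other way (log2 -0.07) and the call was lost with a pseudocount of 1, so it is not read as a difference. The median of each list was placed among 10000 random lists matched on size and expression. Of 32 lists, 6 lay outside the central 95% towards replicate 1 and 8 towards replicate 2, against 1.6 in all expected for randomly drawn genes. Members of a fixed list, and related lists, may vary together, so 1.6 is not the number expected between 2 pools. These placements describe the 2 libraries, and a difference between the pools has no replicate check. Paneth genes and Notch genes lay inside the range here and outside it under 1 alternative each.

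**Figure D3:**
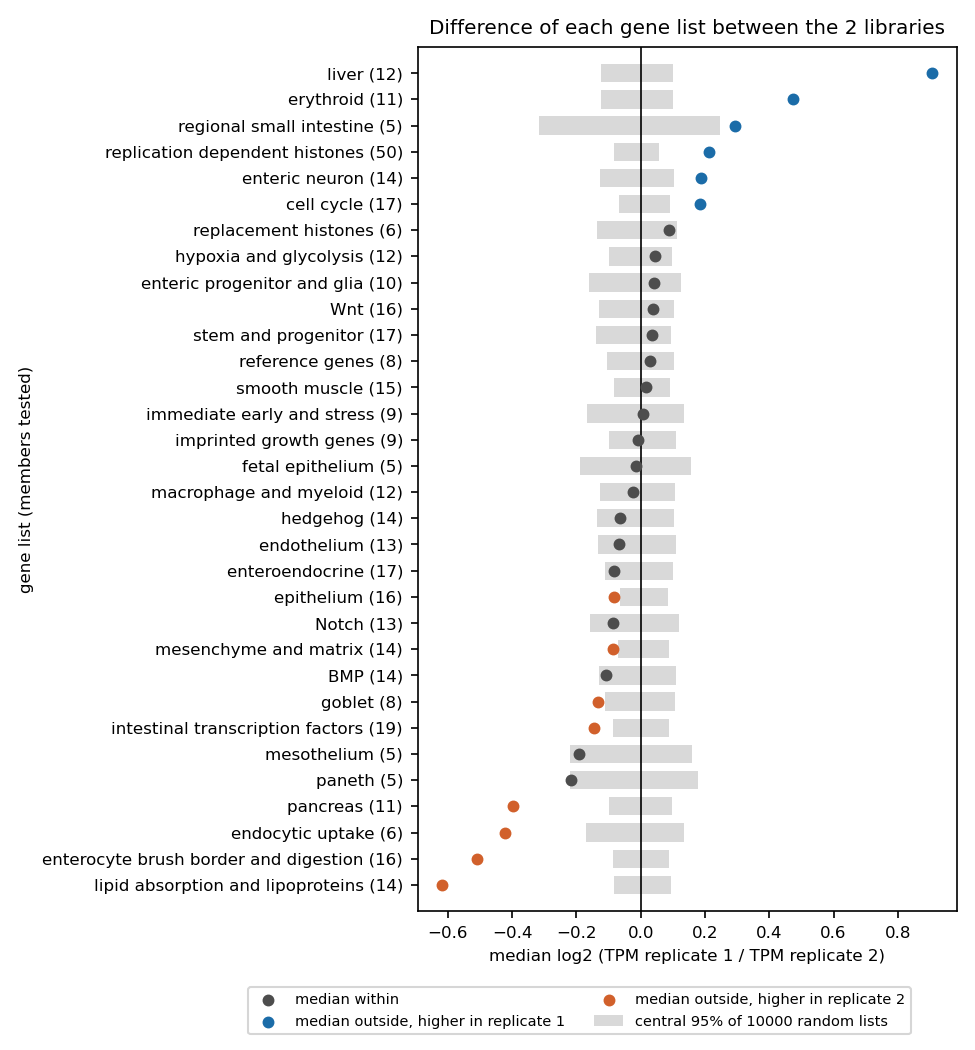
Median log2 ratio of each list, replicate 1 over replicate 2, against the central 95% of 10000 random lists drawn as grey bars. Liver lies farthest to the right, at 1.88-fold, and lipid absorption farthest to the left, at 1.53-fold in favour of replicate 2.

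Single genes at least 2-fold apart were led by steroid synthesis genes known from the adrenal cortex on one side and by Mtch1, Rac1 and Alyref on the other. Fold values of TPM were computed after adding 0.1 and understate low genes. In replicate 1, Cyp21a1 (chromosome 17, 34801348 to 34804561), the 21-hydroxylase, had 737 counts against 3 in replicate 2, a ratio of 236 (95% counting interval 80.4 to 1147). Its intervals of TPM, which also cover read assignment, were 12.1 to 14.5 and 0.0481 to 0.493, and they allow a ratio below 80.4. Cyp11b1, the 11-beta-hydroxylase, read 8.60 and 0.070 TPM, Akr1b7 33.8 and 0.590 and Hsd3b1 13.0 and 0.540. Star, Cyp11a1, Ly6d, the renin gene Ren1, the neutrophil gene Mpo and the antithrombin gene Serpinc1 completed the 10, between 9.64-fold and 3.02-fold. In replicate 2, Mtch1 (chromosome 17, 29332072 to 29347934) read 105 TPM against 22.5, a 4.70-fold difference. The GTPase gene Rac1 (chromosome 5, 143503634 to 143528036) read 187 against 41.1, 4.60-fold, and the mRNA export factor Alyref 73.7 against 16.7, 4.45-fold. Oaf, Aven, Otulin, Actr5, Tmem158, Dapk3 and Inpp5a followed, between 3.74-fold and 3.24-fold. Of 12885 protein-coding genes with a mean count of at least 100, 45 were at least 2-fold higher in replicate 1 and 63 in replicate 2 with intervals of TPM that did not overlap. Of the 45, 6 were liver list genes and 10 were in any fixed list, and of the 63, 3 were. At any fold, intervals were apart for 3389 genes (26.3%). The intervals cover counting and read assignment, not the difference between animals.

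**Figure D4:**
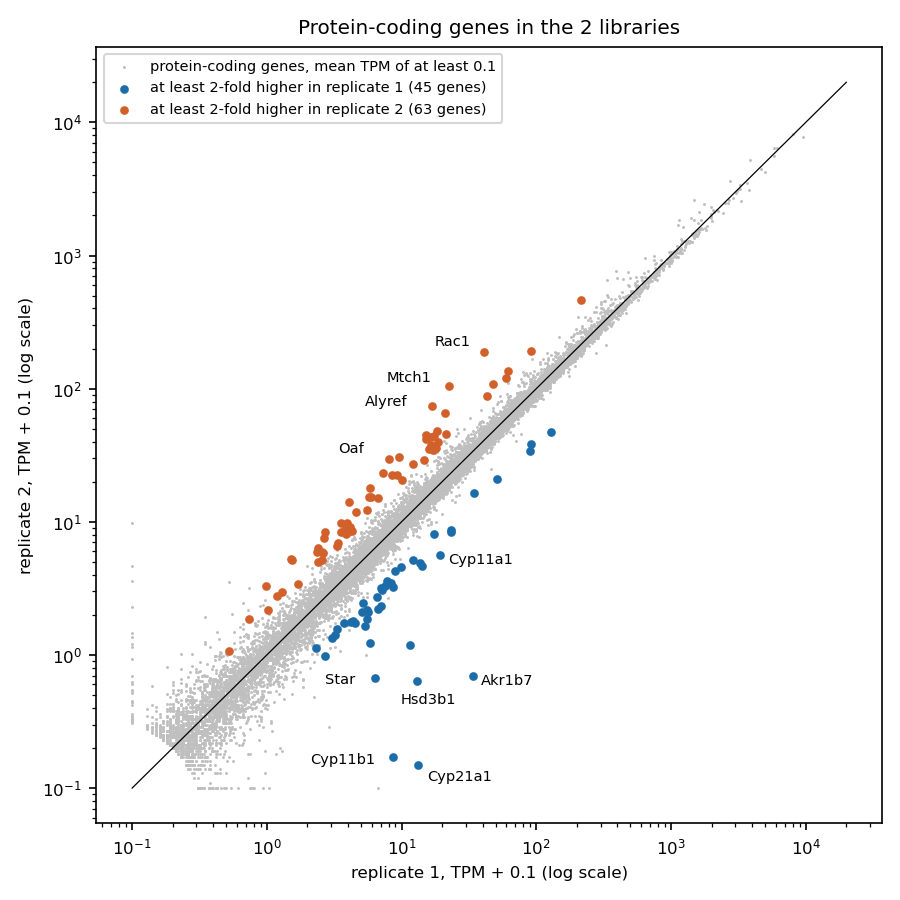
TPM + 0.1 of each protein-coding gene with a mean TPM of at least 0.1, replicate 2 against replicate 1 on log axes, with genes at least 2-fold apart in colour, some of them named, and a line of equality. Of 12885 genes tested, 45 are higher in replicate 1 and 63 in replicate 2.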

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

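The tests on near-identical pancreatic copies, on reads shared with paralogs and on assigned transcript lengths were chosen only after the results were seen, and the genes named from the 5 further lists were chosen after their values were seen. Features with numeric identifiers, which name no gene and enter no comparison, held 61.8 expected counts in replicate 1 and 65.32 in replicate 2, above the 3 that a count of 0 allows. Of the 26248 such features, 11 had a count in either library, the highest 53.

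Pancreatic genes were abundant in both libraries, with Ctrb1 at 1860.5 ± 354 TPM (n = 2). Reads of other genes misplaced onto near-identical copies are argued against, since 83.3% of the list members with counts (10 of 12) had whole-number expected counts in both libraries, within 0.005. Pancreatic tissue carried over with the dissected gut stays open and may account for the pattern: of 13 acinar genes outside the fixed list, 69.2% (9) reached a TPM of 10 in both libraries, led by Prss2 at 153 ± 45.7, Try5 at 139.6 ± 37.6 and Rnase1 at 129 ± 52.0. None of the 13 is in another fixed list, and Gp2 and Reg1 are also known from gut epithelium, Gp2 at 0.635 ± 0.177 and Reg1 at 51.5 ± 5.07. Endocrine genes outside the list followed in 4 of 7 cases at a TPM of 1, with Iapp at 33.4 ± 3.89, and no biological explanation was tested.

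Adrenocortical and liver genes were higher in replicate 1. Steroid synthesis by gut cells alone is argued against for the excess of replicate 1. Mc2r, Mrap and Nr0b1, taken as adrenal-restricted, held 116 counts together in replicate 1 and 7 in replicate 2. Mrap alone held 75 and 5 of these. The argument holds only as far as the 3 genes are restricted to the adrenal, which was assumed and not tested. Cyp11a1 is not covered: it kept 291 counts (5.51 TPM) in replicate 2, where Cyp21a1 had 3 and Cyp11b1 had 6. A source of Cyp11a1 other than adrenal tissue, gut cells included, stays open. Adrenal tissue carried over with replicate 1 may account for the excess of steroid genes there. The 6 adrenal genes outside the fixed list with at least 10 counts in either library had a median log2 ratio of 2.77. With the 2 genes at 0 held at their bounds, the median was 2.09. Those bounds were at least 9.60-fold for Mc2r and 4.70-fold for Cyp11b2, against a floor of 3 counts. All but Inha, the least at 0.13, reached 10 counts only in replicate 1, so the filter itself favoured that side. Mc2r, Mrap and Nr0b1 are among the 6, so this test and the one before it share genes. Liver carried over may account for the liver genes in the same way, with a median log2 ratio of 0.72 over 8 genes outside the fixed list, Serpina6 at 77.2 and 45.9 TPM and Ambp at 46.3 and 24.8, though Fgl1 (-0.75) and F9 (-0.06) went the other way. None of these genes is in a fixed list, 1 of the 8 adrenal genes (Inha) and 5 of the 10 liver genes reached a TPM of 1 in both libraries, and no biological explanation beyond gut steroid synthesis was tested.

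In replicate 2, 63 genes were at least 2-fold higher, among them the broadly expressed Mtch1, Rac1 and Alyref. Genes alike in GC content and length did not share this shift: removing their median moved tested genes by a median log2 of only 0.041 and at most 0.14. The median of 62 of the 63 genes stayed at -1.22, as before. Spearman's rho across genes was -0.0762 with GC and -0.216 with length. With 98.8% of expressed genes within 2-fold, however, such a median could hardly have moved 63 genes picked as outliers. A bias that acts on only some of the genes alike in GC content and length therefore stays open. Reads shared with paralogs are argued against by whole-number counts in 79.4% of the 63 genes, against 73.2% of all tested genes. Lengths assigned differently are argued against by a median log2 ratio of -1.25 in counts without length. No tested explanation accounts for this pattern, no biological one was tested, and its source is open.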

How the results depend on the processing

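None of these alternatives was added after the data were seen. Of 557 values recomputed, 499 kept their direction and their side of the threshold or, without a test, stayed within the spread of the libraries or within 1.5-fold of a count. Among these, Chga over Muc2, not apart, changed sign without replicate 1 (-0.13). Part of the 499 was fixed in advance. For the 22 pairs with either library left out, 1 of 2 values always lies within 1 SD of their mean. Likewise, the 20 genes named as farthest apart could not fail at the looser settings of 1.5-fold or a mean count of 20. Such values are no sign of robustness. The Pearson r was 0.995 with a pseudocount of 0.1, 0.993 for genes with a mean TPM of at least 1 and 0.995 over all genes, and the coefficient of variation was 0.112 without a count filter; the cause was not tested. The top 20 protein-coding genes not encoded by mitochondria held 7.90% of TPM once mitochondrial genes, spike-ins and ribosomal RNA left the total, by construction. Among lists, the Paneth median passed with a pseudocount of 1 (log2 -0.21) and the Notch median with CPM (-0.17), the hypoxia and glycolysis median, which did not pass, changed sign with CPM (-0.0028), and the small intestinal list (0.17) no longer passed with a pseudocount of 1. Genes higher in replicate 1 numbered 80 at 1.5-fold, 7 at 4-fold and 73 with a mean count of 20, and in replicate 2 225 at 1.5-fold and 3 at 4-fold, by construction of each threshold. With TMM counts, 44 of the 45 and 59 of the 63 genes were kept. The major transcript matched in 92.0% of genes at a TPM of at least 1 and in 95.9% at 20. Without length, the histone log2 ratio was 9.22 and that to small structural RNA 11.48, and 6 pairs turned: Apoa1 over Apoa4 (not apart in either unit) to -0.20, Hnf4a over Hnf4g to 0.44, Gli2 over Gli1 to 0.087, Lgr5 over Olfm4 to 0.17, Pdgfra over Pdgfrb to 0.22 and Actg2 over Acta2 to -0.41, of which the Hnf4, Pdgfr and actin pairs became apart and the Gli and Lgr5 pairs no longer were. Detected members fell by over 1.5-fold in 15 of 43 lists at a TPM of at least 5 (replication-dependent histones from 48 to 22, enteroendocrine from 17 to 10, stomach from 3 to 0, colon and hindgut from 2 to 0) and rose in 2 at 0.5 (lymphoid from 2 to 6, urogenital and adrenal from 1 to 3), by construction. With posterior means, small structural RNA rose from 5 to 8 and urogenital and adrenal from 1 to 2, the latter reaching 3 without replicate 2; the cause was not tested. Posterior means turned Notch1 over Notch2 to 0.20 and Lin28b over Lin28a to -0.34; the cause was not tested. Leaving out either library gave 13485 to 13497 detected genes, a top 20 share of 7.33% to 7.44% and 448 to 462 detected list members, against 447 in both. With 1 library per pool, depth limits genes of few counts and the design gives no replicate check of differences between pools.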

Other observations

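The values in this part come from fixed lists, and no test here was chosen after the results were seen. Fetal growth genes were prominent. All 11 imprinted growth genes were detected, with H19 at 1136 ± 12.3 TPM (n = 2), Igf2 at 653 ± 13.6, Mest at 493 ± 1.40 and Igf2r, which clears IGF2, lowest at 27.5 ± 5.60. Of 6 oncofetal RNA-binding and chromatin genes, 4 were detected, Igf2bp2 at 83.8 ± 0.049, Igf2bp3 at 61.7 ± 2.63, Igf2bp1 at 33.3 ± 1.46 and Hmga2 at 17.0 ± 1.56, while Lin28b and Lin28a stood at 0.310 ± 0.085 and 0.080 ± 0. All 12 hypoxia and glycolysis genes were detected, from Ldha, Eno1 at 1693 ± 114 and Aldoa at 1009 ± 39.4 to Vegfa at 2.59 ± 0.368. Immediate early and stress genes were detected in 9 of 11 cases, with Ier2 at 66.8 ± 0.693, Jun at 61.1 ± 3.68 and Junb at 18.4 ± 4.27 highest and Fosb lowest at 0.115 ± 0.049. Among nuclear long noncoding RNAs, all 5 detected, Malat1 stood at 2416 ± 267, Neat1 at 40.0 ± 6.15, Airn at 16.3 ± 1.56, Tsix at 4.52 ± 0.849 and Kcnq1ot1 at 2.40 ± 0.184. Whether libraries kept strand is not given, so values of the antisense RNAs Airn, Tsix and Kcnq1ot1 may include reads of overlapping genes.

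Sex-linked genes differed between the mixed-sex pools in opposite directions. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d read 24.9, 15.6, 7.24 and 5.61 TPM in replicate 1 and 14.1, 9.42, 4.23 and 3.60 in replicate 2, and Xist, which silences the inactive X chromosome, read 14.4 and 23.1. The intervals of all 5 were apart. These opposite directions argue against 2 preparations of 1 pool of embryos, a question that the chi-square could not settle. That reading was made after the values were seen.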
